A study of Homo sapiens with 6 samples.

How the data were processed

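RNA from 6 cultures of SHEP-SF, an established human neuroblastoma cell line, was measured on 1-colour Affymetrix arrays of the HG-U133 set (A), as the probe set names show. Each culture came from 1 of 3 clonal derivatives of the line, named in the labels as iA50 clone 6, iA50 clone 9 and iFA50 clone 8, and each clone gave 1 culture marked + and 1 marked −. The labels describe an inducible system and do not say what + stands for, so every difference is given as + minus −, and its sign is not read as induction.

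The values were intensities on a linear scale as deposited by the authors, whole numbers for 22283 probe sets per array. The software, background correction and scaling that made them are not given in the sources used here. Between 61.2% and 62.8% of the values from 10000 to 50000 ended in 0, against 9.8% to 10.4% of those from 1000 to 10000, and of those from 50000 upward 9.3% to 10.9% did. The reason for this break in the digits is not known here, and it could not be checked whether the values below and above it share 1 scale. Differences are given as ratios of the deposited values, and the absolute scale stays unknown. Ratios of values on either side of 10000 or 50000 would not hold if the scales differ. Among the genes named below, this applies to GLUL and CXCL12, for example. Median intensities ranged from 2868 to 3180 over the 6 arrays, the highest 1.11 times the lowest, under the limit of 1.5 times set for further scaling, and the values were used as deposited. The number of arrays, and not a count of reads, limits the precision.

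The 68 control probe sets were left out of the tests. Values were transformed as log2(intensity + 16), and the 40% of probe sets with the lowest mean over all arrays were left out, which kept 13329 of 22215 and corresponded to a mean intensity of about 1788. The offset shrinks the log2 differences of dim values only slightly at the levels kept. In clone 8, 326 probe sets differed at least 2-fold with it, against 328 with an offset of 1. Large differences of dim probe sets are therefore not conservative. Gene symbols came from the platform annotation: 19071 probe sets had 1 symbol, 1043 had several and 2169 had none, and only probe sets with 1 symbol were named. Of the 19071, 19059 matched the RefSeq gene table of GRCh38.p14 by Entrez identifier and 0 needed a new symbol. That table was used for names only.

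Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-dependent prior variance), with Benjamini-Hochberg adjustment over the 13329 probe sets and a threshold of 0.05. All linear models used the 6 arrays. The first compared + with − over the 3 clones with clone as a block, which left 2 residual degrees of freedom. The second gave the iA50 clones and the iFA50 clone a response each, again with clone as a block, and yielded the iA50 response and the difference between the responses with 1 residual degree of freedom, where the test leans on the prior (14.4 prior degrees of freedom, against 6.58 in the first model). The lone iFA50 pair was there assumed to vary like the iA50 pairs. A further contrast set clone 8 against the mean of clones 6 and 9 with state as a block. The pair of clone 8 alone was described by its log2 differences, without a test. The cultures of 1 clone have no separate repeats, so p-values measure the spread left between these arrays after the terms of each model. In the contrast of clone 8 with clones 6 and 9, the spread between clones is therefore not part of the error.

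The pairing came from the titles, which give a + and a − culture of the same clonal line, and was written into the model before the data were examined. The correlation of the deviations from the state means between the arrays of a clone was 0.65 for clone 6, 0.66 for clone 9 and 0.72 for clone 8. Without the replicate block, the number of probe sets past the threshold was 0 in all 3 clones and 0 in the iA50 clones.

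The 19 gene lists, with 432 entries, were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the brightest on average), over 8061 genes. They covered APP processing, literature AICD targets, actin and SRF targets, matrix and TGF-beta genes, stress responses (unfolded protein, heat shock, p53, hypoxia), cell division, cholesterol synthesis, interferon and immediate early genes, oxidative phosphorylation, ribosomal proteins, and markers of noradrenergic, mesenchymal, Schwann, epithelial and blood cells. The lists were planned for the comparison of all 3 clones, and their tests on the other contrasts were added after seeing the data. For the single pair of clone 8, the median of each list was placed among 10000 random lists of the same size matched on mean level.

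Named genes followed a rule fixed before the data were examined: APP, APBB1, APBB2, KAT5, TAGLN and ACTA2 always, then up to 10 genes per direction with the largest differences past the threshold, filled with genes that differed the same way in every clone, ranked by their smallest difference. For the clone 8 pair and for the difference of responses the 10 largest differences each way were taken. For each list, members were named by the largest absolute mean difference over the 3 clones. List members named in other comparisons, and further probe sets of a named gene, were chosen after their values were seen.

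On simulated data with 13329 probe sets and 5 sets of 200 changes, the comparison of all 3 clones recovered 83.2% of 2-fold and 98.8% of 4-fold changes, with 6.67% false calls. The iA50 response recovered 80.4% of 2-fold and 99.0% of 4-fold changes, the difference of responses 40.4% and 86.8%, and false calls made up 19.3% and 20.3% of their calls, above the nominal 5%. The clone comparison recovered 83.0% and 99.2%, with 8.17% false calls. Its simulated errors held no variation between clones, so these shares do not cover it. A shift of 0.5 (log2) put into the actin list was found by camera in 20 of 20 simulated sets, and 0 sets without a shift gave a list. The simulated genes varied independently of each other, with the same spread on every array. The 0 false lists therefore do not check the list test under inter-gene correlation.

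The alternatives tried were other offsets, quantile and median scaling, no filter and a stricter filter, 1 prior variance, the fit without the block, leaving out each clone, leaving out _x_at probe sets, an estimated inter-gene correlation, fry, and averaging the probe sets of a gene. An offset of 500 and scaling to the spike-in probe sets were chosen after seeing the data. The estimated inter-gene correlation rests on 1 or 2 residual degrees of freedom, so that list test has little power. A list lost there is not shown to be a false call, and the preset value stays unchecked. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.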

Results

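Expression was measured in SHEP-SF, a human neuroblastoma cell line, to look for genes that respond to the amyloid precursor protein intracellular domain (AICD), the fragment released into the cytosol when gamma-secretase cuts the precursor protein APP. The 6 arrays came from 3 inducible clones, with 1 array of a + culture and 1 of a − culture each: iA50 clone 6, iA50 clone 9 and iFA50 clone 8. The + and − states thus had 3 arrays each, iA50 had 2 clones and iFA50 had 1, so the construct and the clone cannot be told apart. All signed values are + minus − on the log2 scale unless a sentence names another direction. Arrays of 1 clone resembled each other most (Pearson correlations of 0.980, 0.976 and 0.973 across probe sets, which are not independent replicates), clones 6 and 9 correlated at 0.946 to 0.951, and clone 8 correlated with them at 0.901 to 0.920. Clone accounted for 78.0% of the sum of squares, state for 7.43% on 1 degree of freedom, and the rest for 14.6% on 2, so state carried about as much per degree of freedom as the rest. The ratio of the 3′ to the 5′ ACTB control probe set, a sign of RNA integrity, was 1.47 and 1.37 on the + and − arrays of clone 8, against 0.943 to 1.09 on the other 4 arrays. The same ratio for GAPDH differed less, 0.929 and 0.967 in clone 8 against 0.879 to 0.899. The 18 hybridisation spike-in probe sets were also brighter in clone 8 (median log2 difference 0.61, SD 0.18).

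The genes that frame the study were read first on each array. APP itself, on its brightest probe set, had intensities of 31120 and 36309 in clone 6 (+ and −), 24265 and 21800 in clone 9, and 15970 and 22309 in clone 8, a mean difference of −0.18 ± 0.13 (SE, n = 3 clones; limma adjusted p = 0.96). The 3 APP probe sets shared a direction in clone 9 (0.15, 0.11 and 0.38) and not in clones 6 and 8. APBB1, which encodes the AICD-binding adaptor FE65, was lower in the + culture of each clone (1914 against 3211, 1412 against 2564 and 2810 against 3968), but its mean difference of −0.70 ± 0.22 did not pass (limma adjusted p = 0.96). No probe set of APBB2, a relative of FE65, or of KAT5, the histone acetyltransferase TIP60, passed either. Where these probe sets lie relative to any introduced construct is not known here, so they do not check the labels. TAGLN, an actin-binding protein of smooth muscle and fibroblasts, and ACTA2, smooth muscle alpha-actin, are known to have been followed by the study as genes raised with AICD. TAGLN differed by −0.01 in clone 6, −0.03 in clone 9 and −1.79 in clone 8, and ACTA2 by 0.11, −0.23 and −1.43. In clone 8 these signs run opposite to the study's if + marks AICD expression, and the same way if − marks it. The labels do not say which, so the clone 8 values neither bear out nor contradict the study. In clones 6 and 9 the differences were small.

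**Figure D1:**
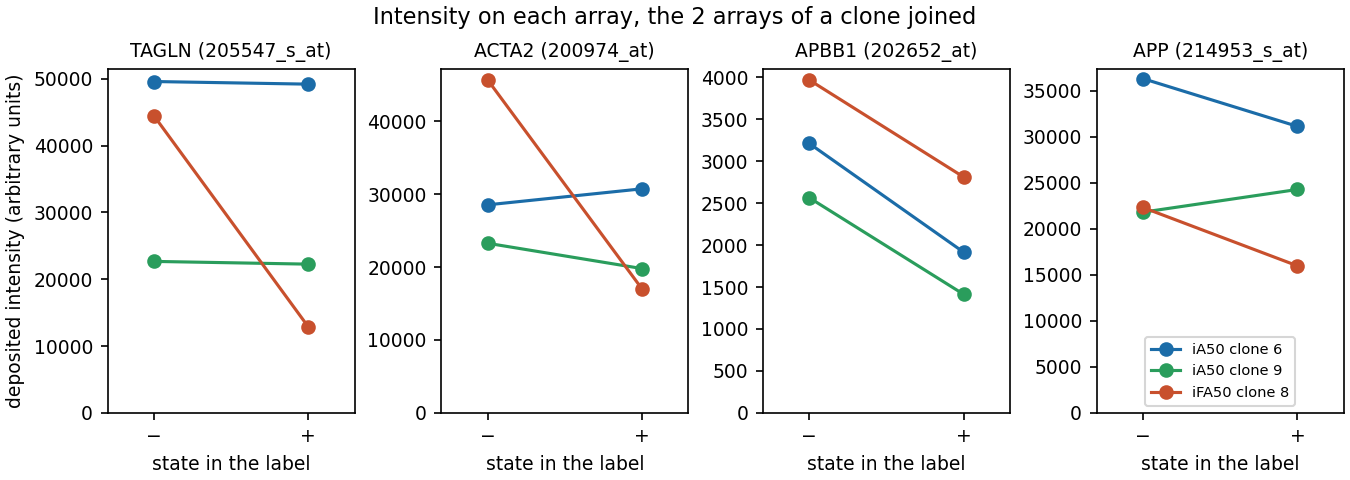
Deposited intensity (arbitrary units, linear axis from 0) of TAGLN, ACTA2, APBB1 and APP on each of the 6 arrays, with the − and + array of a clone joined by a line and 1 colour per clone. In clone 8, TAGLN went from 44462 (−) to 12851 (+) and ACTA2 from 45727 to 17013, while APBB1 was lower on the + array of all 3 clones.

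No gene passed the test of + against − over all 3 clones. The lowest adjusted p belonged to a probe set of IGHG1, an immunoglobulin heavy chain constant region gene, with −1.45 ± 0.16 (limma adjusted p = 0.150) and the same direction in 3 of 3 clones (−1.11, −1.50 and −1.75). No other probe set of IGHG1 was kept, so whether this signal comes from that gene could not be checked. PLCD1, a phospholipase C that cleaves phosphatidylinositol bisphosphate, was ranked first on the higher side by the smallest of its 3 differences, 0.99, 1.44 and 1.64 (mean 1.36 ± 0.19, limma adjusted p = 0.359). The count was 0 of 13329 probe sets, with 617 (4.63%) at an unadjusted p under 0.05.

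Other genes higher in the + culture of each clone, none past the threshold (limma adjusted p = 0.963 for each), were MMP24OS (mean 1.57), NIPAL3 (1.42), PRSS3P2 (1.01), the deubiquitinase USP48 (0.95), the mitochondrial thiolase ACAA2 (0.88), the G protein subunit GNB5 (0.83), the mitochondrial protease YME1L1 (0.83), PRB1 (0.76) and CHGB (0.74), a granin of neuroendocrine secretory granules. Lower in each clone, likewise not past it, were CFAP70 (−1.31), APOL2 (−1.12), the autophagy factor ATG13 (−1.40, −0.72 and −0.86 in clones 6, 9 and 8), GUCA2A (−0.86), the RNA-binding protein BICC1 (−0.77), the synaptic vesicle protein SYNGR1 (−0.76), C2CD2L (−0.75), APBB1 (−0.70) and the peroxisomal carnitine acyltransferase CROT (−0.69). Further probe sets of MMP24OS, YME1L1 and ATG13 did not all share these directions, and neither other kept probe set of SYNGR1 did. With clone 8 left out, 28 probe sets passed, among them IGHG1, PLCD1, CFAP70 and CROT (limma adjusted p = 4.5e-04, 0.017, 0.032 and 0.035). That fit has the same estimates as the iA50 response given below, which had 13 calls, and differs from it in the prior variance. PLCD1 and CFAP70 did not pass in the iA50 response (limma adjusted p = 0.059 and 0.142). With clone 6 left out 1 passed, IGHG1 (limma adjusted p = 0.036), and with clone 9 left out 0. Over all alternatives the limma adjusted p ran from 4.5e-04 to 1.0 for IGHG1, from 0.017 to 1.0 for PLCD1, from 0.032 to 1.0 for CFAP70 and from 0.035 to 1.0 for CROT.

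None of the 19 gene lists passed in all 3 clones (camera, lowest adjusted p = 0.446), and 0 of their members rose or fell, over all probe sets or adjusted over the list alone. Among 19 measured genes of APP processing (median −0.02), ADAM9, a metalloprotease that can cut APP, stood at 0.30 ± 0.09 and APH1B, a gamma-secretase subunit, at 0.31 ± 0.13. Among 10 proposed AICD targets (median 0.0017), CD82 stood at 0.56 ± 0.29 and LRP1 at −0.42 ± 0.28. The 22 actin and SRF genes had a median of −0.06, with ACTG2 at 0.92 ± 0.29 and TAGLN at −0.61 ± 0.30, and the 27 matrix genes a median of −0.02, with COL6A3 at −0.40 ± 0.25 and LOX at −0.33 ± 0.19. The stress lists lay near 0: unfolded protein response −0.02 (DDIT3 0.29, ATF3 0.28), heat shock −0.02 (HSPH1 −0.27, DNAJB1 −0.13), p53 targets 0.06 (SESN1 0.40, PLK3 0.34), and hypoxia 0.0011 (ENO2 0.32, DDIT4 0.27).

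The medians of the other lists in all 3 clones were 0.01 for cell division (MCM5 −0.24, CCNB2 0.22), −0.04 for cholesterol synthesis (SREBF2 0.21, HMGCS1 −0.19), −0.03 for interferon response (IFIT2 0.67, IFIT1 −0.38), 0.04 for immediate early and NF-kB genes (MYC −0.65, CCL2 0.36), 0.03 for oxidative phosphorylation (COX6C 0.16, COX7B −0.13) and −0.0040 for ribosomal proteins (RPL22 0.20, RPL11 −0.19). Markers of other cell types or states did not pass either. Their medians were 0.04 for noradrenergic (CHGB 0.74, ELAVL4 −0.36), 0.13 for mesenchymal (NES 0.45, NOTCH3 0.25), 0.25 for Schwann cell (2 genes, ERBB3 0.46 and ERBB2 0.04), −0.16 for epithelial (OCLN 0.28, KRT8 −0.21) and 0.05 for blood cell markers (CD3D 0.08, CD3E 0.05). Leaving out clone 6 let the actin and the matrix list pass as lower (camera adjusted p = 0.0068 for each, adjusted p = 0.88 with an estimated correlation). Leaving out clone 8 let the mesenchymal list pass as higher (adjusted p = 0.0056, adjusted p = 0.999 with an estimated correlation).

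In the iA50 clones alone, 6 named genes rose in the + cultures and 4 fell, as single calls that no tested gene group covers. DUS2, a tRNA dihydrouridine synthase, rose by 1.76 ± 0.23 (limma adjusted p = 0.0037), CYLD, a deubiquitinase that restrains NF-kB, by 1.53 ± 0.26 (limma adjusted p = 0.026), and PVR, the poliovirus receptor, by 1.39 ± 0.22 (limma adjusted p = 0.016). PEX5, the import receptor of peroxisomes, rose by 1.18, SLC7A11, the cystine-glutamate exchanger, by 0.87, and HLA-G by 0.84. GLUL, glutamine synthetase, fell by 1.32 ± 0.18 on the log2 scale (from 16512 to 8592 in clone 6 and from 19552 to 6000 in clone 9; limma adjusted p = 0.0037). MED27, a Mediator subunit, fell by 1.87, the acid-sensing channel gene ASIC1 by 1.79, and the lone kept probe set of IGHG1 fell too (−1.11 and −1.50 in clones 6 and 9). These are the 10 named genes among 13 probe sets past the threshold (8 higher, 5 lower; 3 without a symbol), with 1156 at an unadjusted p under 0.05.

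Each of these genes had the same direction in both iA50 clones. PVR, SLC7A11, HLA-G and GLUL had other probe sets that did not all share it, and the HLA-G probe set is of a kind (_x_at) that can read related HLA genes. Probe sets of this kind, which can read related sequences, also gave the values named in this report for other genes. Among these are PRSS3P2, PRB1, GNB5, APOL2, CFAP70, ATG13, CD6, PDLIM7, CD300C, TNFRSF25, SRSF1, PRDX2 and FN1. Among genes that did not pass, PLCD1 stood at 1.21 (limma adjusted p = 0.059), USP48 at 1.06, PDLIM7 at 0.94 and 1.07 in clones 6 and 9, and PRSS3P2 at 0.97, and on the lower side HBB at −1.71, CFAP70 at −1.59, PAQR5 at −1.33, CD6 at −1.29, ZGPAT at −1.20 and CIAO3 at −0.87. HBB stood at −0.84 in clone 6 and −2.58 in clone 9, and neither of its other probe sets shared its direction. Of the 3 other probe sets of PDLIM7 only 1 shared its direction. Of the lists, the mesenchymal markers shifted upward (median 0.20; camera adjusted p = 0.0067, adjusted p = 0.99 with an estimated correlation), with 0 of 13 members past the threshold over all probe sets or adjusted over the list alone. NES stood at 0.75 and 0.46 in clones 6 and 9, and NOTCH3 at 1.62 and −0.92. The 13 calls became 2 with quantile normalization, 0 without the block and 0 with 1 prior variance or no filter. The same pairs fitted without the clone 8 arrays gave 28. With median scaling 8 were higher and 11 lower, and with quantile normalization 1 and 1, against 8 and 5 as deposited.

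In clone 8, the largest differences between its + and − array included EFNB3, a transmembrane ephrin, with 7493 against 1189 (2.64), and SH2B1, a signalling adaptor of receptor kinases, with 455 against 5512 (−3.55). TAGLN was 3.46-fold lower in the + culture and ACTA2 2.69-fold lower. This pair has no replicate and no test. Further genes higher in + were LOC100288570 (3.01), the pyrimidine enzyme UMPS (2.61), the mRNA export factor THOC6 (2.60), TAF1 (2.49), GDF3 (2.39), the retinoid receptor RXRB (2.33), IL23A (2.26), PIDD1 (2.21) and SLC8B1 (2.19). Lower in + were RNF39 (−2.72), the ETS factor ELF4 (−2.68), CEACAM5 (−2.62), EPS8L3 (−2.55), CD300C (−2.34), NPR3 (−2.26), the natriuretic peptide clearance receptor, the folate carrier SLC19A1 (−2.11), PHF24 (−2.09) and TNFRSF25 (−2.09). No other kept probe set of UMPS, TAF1, RXRB, ELF4 or CEACAM5 shared the direction, and of the 2 others of TNFRSF25 only 1 did. In all, 326 probe sets differed at least 2-fold (151 higher, 175 lower), against 197 in clone 6 and 229 in clone 9. In the brighter 6664 probe sets the counts were 28, 6 and 9. Some of the genes named here lay close to the filter limit of 10.82 (mean log2 level), such as CEACAM5 (10.82), IL23A (10.82) and CD300C (10.85). Others with a higher mean rest on a low + array of clone 8, such as SH2B1 (455), RNF39 (479) and ELF4 (565).

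Some genes of the contractile cytoskeleton and the extracellular matrix, 4 of 22 and 4 of 27 measured, were lower in the + culture of clone 8 and passed a test of its response against that of the iA50 clones. That test assumes that the lone clone 8 pair varies like the iA50 pairs, which could not be checked, and the SD over all probe sets was 0.39 in clone 8 against 0.32 and 0.35 in clones 6 and 9. Both list calls were lost with an estimated correlation (camera adjusted p = 0.82). With 1 residual degree of freedom that test has little power, so it does not decide whether the list calls hold. For TAGLN the difference of responses, clone 8 minus the iA50 mean, was −1.77 ± 0.18 (limma adjusted p = 2.8e-04), and for ACTA2 −1.36 ± 0.20 (limma adjusted p = 0.0047). FN1, fibronectin, differed by −1.17 ± 0.13 (limma adjusted p = 4.8e-04), ACTN1, an actin cross-linker, by −1.13 ± 0.16 (limma adjusted p = 0.0037), and COL4A1, a basement membrane collagen, by −1.07 ± 0.17 (limma adjusted p = 0.0075). The 3 genes stood at −1.02, −0.77 and −0.91 in clone 8, against 0.07, 0.45 and 0.21 in clone 6 and 0.23, 0.27 and 0.11 in clone 9. The 5 kept FN1 probe sets were all lower in clone 8, and 3 of them passed. None of the calls of this test held without a filter or with 1 prior variance.

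Of 22 measured actin and SRF genes, 4 had a lower response in clone 8 (TAGLN, ACTA2, ACTN1 and the tropomyosin TPM4 at −0.90) and 0 a higher one, or 6 and 0 adjusted over the list alone (median −0.26; camera adjusted p = 9.3e-07, adjusted p = 0.82 with an estimated correlation). TAGLN and ACTA2 entered this list from the study, so the list is not independent evidence. Of 27 matrix and TGF-beta genes, 4 were lower (FN1, COL4A1, the cross-linking enzyme LOX at −0.97 and the TGF-beta and BMP target ID3 at −0.82) and 0 higher, or 10 and 1 adjusted over the list alone (median −0.24; camera adjusted p = 3.2e-07, adjusted p = 0.82 with an estimated correlation). Of 13 mesenchymal markers, 2 were lower (FN1, shared with the matrix list, and IL6ST at −0.88), or 4 adjusted over the list alone (median −0.38; camera adjusted p = 3.1e-04, adjusted p = 0.82 with an estimated correlation). PMAIP1, a pro-apoptotic p53 target, was the lone member called in the p53 list (−0.91). Within clone 8 the ACTB ratio was 1.47 and 1.37 and the spike-ins differed by 0.06 between the arrays.

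**Figure D2:**
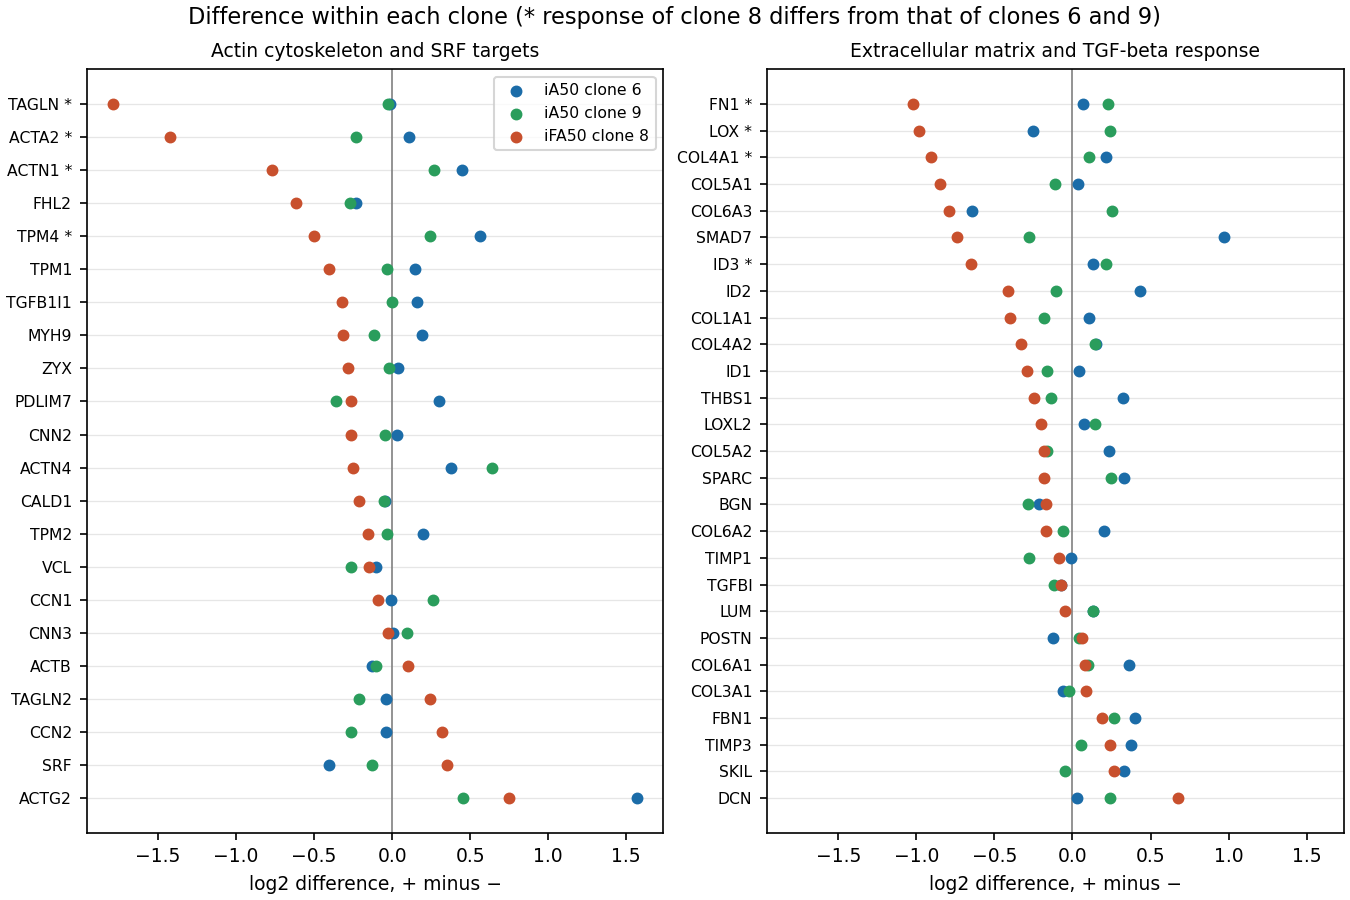
Log2 difference (+ minus −, horizontal axis) of each measured gene of the actin and SRF list (left) and of the matrix and TGF-beta list (right), with 1 point per clone. Genes are ordered by their value in clone 8, and a star marks an adjusted p under 0.05 for the difference of responses between clone 8 and the iA50 clones. In clone 8, 37 of the 49 genes lay below 0, with TAGLN (−1.79), ACTA2 (−1.43) and FN1 (−1.02) farthest out.

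In all, 141 probe sets (117 genes; 60 higher, 81 lower; 19 without a symbol) passed this test of a different response in clone 8, with 1825 at an unadjusted p under 0.05. By size the list was led on the higher side by SLC8B1, a mitochondrial sodium-calcium exchanger (3.56), HCFC1R1 (3.11), LOC100288570 (3.07), EFNB3 (2.81), PIDD1 (2.77), THOC6 (2.64), GLB1L2 (2.53), UMPS (2.49) and ASIC1 (2.45). TBX2 (2.43) did not pass (limma adjusted p = 0.071). On the lower side stood SH2B1 (−3.49), CD300C (−3.16), EPS8L3 (−3.13), CEACAM5 (−3.02), ELF4 (−2.98), RNF39 (−2.82), IGFBP3 (−2.66), a binding protein of insulin-like growth factors, SLC19A1 (−2.61), GPR107 (−2.53) and the splicing factor SRSF1 (−2.51). IGFBP3 had a second probe set at −1.60 (limma adjusted p = 0.0037), while no other kept probe set of PIDD1, CEACAM5 or GPR107 shared the direction and those of UMPS and SRSF1 did so only in part. For ASIC1 the difference came mostly from the iA50 clones (−1.94 and −1.64, against 0.66 in clone 8). It came partly from clone 9 for IGFBP3 (2.14, first probe set), PIDD1 (−1.50) and CD300C (1.29), and partly from clone 6 for SLC8B1 (−2.33), HCFC1R1 (−1.63), ELF4 (1.21) and SLC19A1 (1.15). Many of these leading differences rest on arrays far below the filter limit, a mean intensity of about 1788. On the clone 8 − array LOC100288570 read 264, UMPS 280 and THOC6 430, and on its + array SH2B1 read 455 and RNF39 479. SLC8B1 read 568 on the clone 6 + array and 727 on the clone 8 − array. The 141 calls became 11 with quantile normalization, 91 with the offset raised to 500, 416 with the stricter filter, and 0 without a filter or with 1 prior variance. The higher and lower calls numbered 5 and 6 with quantile normalization and 108 and 71 with median scaling.

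Clone 8 differed from clones 6 and 9 across much of the array, in both states. The SEs and p-values of this comparison leave out the spread between clones 6 and 9, so they describe these arrays and not clones in general. As lists, cell division and heat shock genes were higher in clone 8, and cholesterol synthesis, immediate early and unfolded protein response genes were lower. None of these 5 lists passed with an estimated correlation (camera, lowest adjusted p = 0.50), but with 2 residual degrees of freedom that test has little power. CENPF, a kinetochore protein of dividing cells, was higher by 1.81 ± 0.13 (limma adjusted p = 7.3e-05), CDC20, the activator of the anaphase-promoting complex, by 1.45 ± 0.12 (limma adjusted p = 1.4e-04), and MKI67, the Ki-67 proliferation antigen, by 1.29 ± 0.11 (limma adjusted p = 1.3e-04). SCD, the desaturase that makes monounsaturated fatty acids, read 690 and 445 in clone 8 (+ and −), 8050 and 6960 in clone 6, and 12597 and 12170 in clone 9 (−4.08 ± 0.20, clone 8 minus the others; limma adjusted p = 3.6e-05). The chemokine CXCL12 read 3634 and 3174, against 14225 and 14890 in clone 6 and 44916 and 52576 in clone 9 (−2.96 ± 0.13; limma adjusted p = 2.2e-05).

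Of 34 cell division genes, 31 were higher in clone 8 and 0 lower, or 32 and 0 adjusted over the list alone (median 0.93; camera adjusted p = 4.0e-15, adjusted p = 0.50 with an estimated correlation). Of 11 heat shock genes, 9 were higher (HSP90AA1 0.85, HSPD1 0.73) and 1 lower (HSPB1 −0.65), with the same counts adjusted over the list alone (camera adjusted p = 0.0089, adjusted p = 0.50 with an estimated correlation). Of 13 cholesterol genes, 0 were higher and 6 lower (INSIG1 −1.53, DHCR7 −1.51), or 8 lower adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.50 with an estimated correlation). Of 22 immediate early and NF-kB genes, 2 were higher (CXCL2 0.80, NFKBIA 0.52) and 9 lower (EGR1 −2.27, EGR3 −2.08, CCL2 −1.78), with the same counts adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.50 with an estimated correlation). Of 19 unfolded protein response genes, 0 were higher and 6 lower (the chaperone CALR −1.88, VLDLR −1.52), again with the same counts over the list alone (camera adjusted p = 0.0089, adjusted p = 0.63 with an estimated correlation). These counts stand against 3078 probe sets higher and 1910 lower among all 13329 in this contrast. The unfolded protein response list had no larger share of calls than that in total, though all of its calls were lower. The matrix list did not pass, with 6 genes higher and 6 lower (median 0.01; camera adjusted p = 0.364). The ACTB ratio and the spike-ins were also higher in clone 8, as given above for the arrays, and move with each of these groups.

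**Figure D3:**
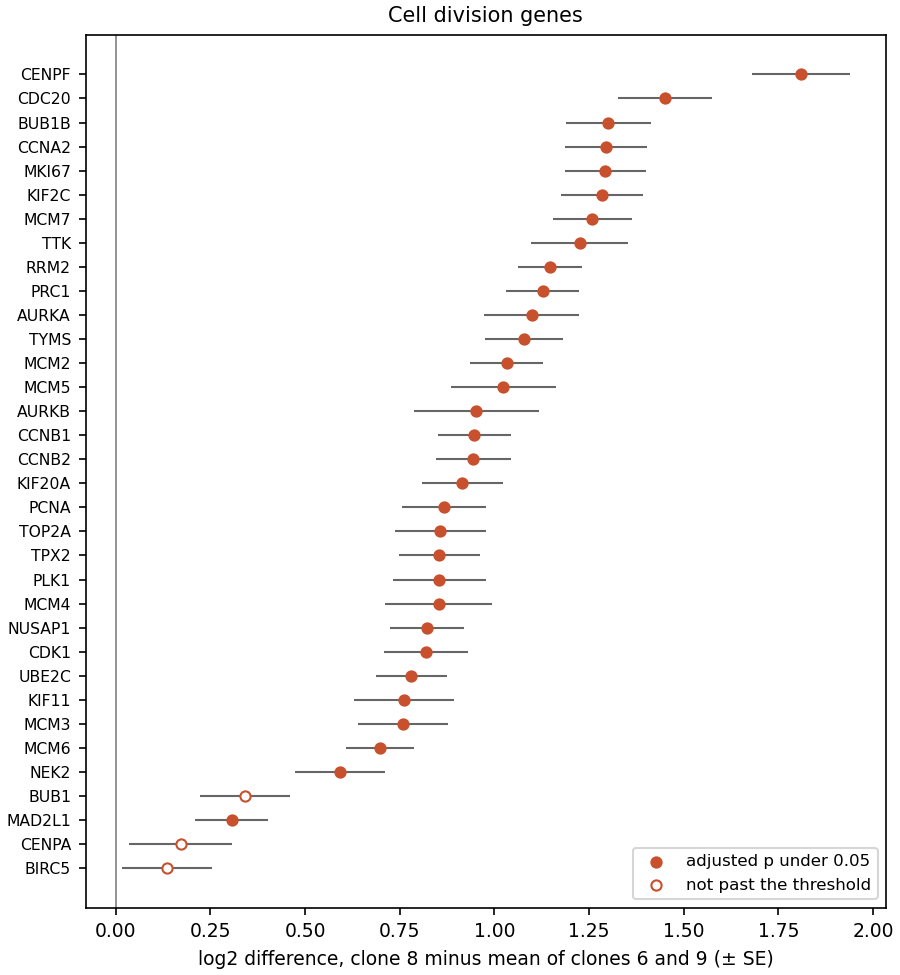
Log2 difference (clone 8 minus the mean of clones 6 and 9, horizontal axis) of the 34 measured cell division genes, with bars of 1 SE from the limma model over the 6 arrays. The bars leave out the spread between clones 6 and 9. Filled points passed an adjusted p of 0.05 and open points did not. All 34 lie above 0, and 31 passed.

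Other genes higher in clone 8, named by size, were TAOK1 (3.57), the chromatin remodeller HELLS (3.23), SEMA3D (2.97), ADD2 (2.83), DNAJC7 (2.70), PRDX2 (2.67), GOLGA4 (2.62), PEG10 (2.60), SERPINB7 (2.60) and DNAJC15 (2.47). Lower were the laminin chain LAMA4 (−3.51), ZSCAN18 (−2.95), the growth factor binding protein IGFBP5 (−2.89), TFPI (−2.72), an inhibitor of blood coagulation, CORO1B (−2.70), COLEC12 (−2.63), the selenium carrier SELENOP (−2.60) and the tryptophan-degrading enzyme IDO1 (−2.56). PEG10 rests on clone 6, where it read 310 and 411, against 17520 and 15290 in clone 9 and 12680 and 17770 in clone 8. Without clone 6 its difference was −0.12 (limma adjusted p = 0.65, with a range from 3.0e-05 to 0.65 over the alternatives). SERPINB7 rests largely on clone 9, where it read 348 and 422, against 7549 and 5722 in clone 6 and 10250 and 9402 in clone 8, and without clone 9 its difference was 0.58 (limma adjusted p = 0.034, with a range from 4.2e-06 to 0.034 over the alternatives). ADD2 leans on clone 6, where it read 322 and 321, and without that clone its difference was 1.08 (limma adjusted p = 0.0019, with a range from 8.9e-05 to 0.0036). The other probe sets of PRDX2 did not share its direction, and of the 2 others of ADD2 only 1 did. In all, 4988 probe sets passed (3078 higher, 1910 lower, 3511 genes), 61.7% of them higher, against 49.5% with quantile normalization. With arrays scaled to the spike-ins, 8377 passed and 5.32% were higher, since that scaling moved the median of all probe sets from 0.06 to −0.60. This comparison is between 3 clonal lines, and the 2 arrays of a clone are not independent clones.

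Whether the clones responded alike was examined across probe sets. In all 3 clones, 21 probe sets differed at least 1.5-fold the same way (14 higher, 7 lower), against 4, 10 and 17 after turning the sign of clone 6, 9 or 8. At 2-fold the count was 2 against 0, 0 and 0. These 4 sign patterns are too few to exclude chance. Across the 13329 probe sets, which are not independent replicates, the differences of clones 6 and 9 correlated weakly (Pearson 0.0992, Spearman 0.112), and those of clone 8 did not run with either (−0.0240 and −0.0127 with clone 6, −0.0472 and −0.0628 with clone 9). The share of probe sets with the same sign was 54.1% for clones 6 and 9, 49.0% for clones 6 and 8 and 47.3% for clones 9 and 8.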

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

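All tests in this part were chosen after the results they weigh had been seen. A test of the difference between the responses of iFA50 clone 8 and of the iA50 clones passed for 141 probe sets, and the results named here were picked out for that reason. The test has 1 pair of clone 8, takes its spread from the 2 iA50 pairs, and gave 20.3% false calls in simulation, so single calls are uncertain. That simulation gave every array the same spread per probe set, so it does not give the false share among the 141 calls. As values, the difference of responses (clone 8 minus iA50, log2) was 3.56 for SLC8B1, 3.11 for HCFC1R1, 3.07 for LOC100288570, 2.81 for EFNB3, 2.77 for PIDD1, 2.64 for THOC6, 2.53 for GLB1L2, 2.49 for UMPS and 2.45 for ASIC1. It was −3.49 for SH2B1, −3.16 for CD300C, −3.13 for EPS8L3, −3.02 for CEACAM5, −2.98 for ELF4, −2.82 for RNF39, −2.66 for IGFBP3, −2.61 for SLC19A1, −2.53 for GPR107 and −2.51 for SRSF1. Many of these values rest on arrays far below the filter limit, as given above. Among genes past the threshold in the iA50 clones the difference of responses was −2.21 for CYLD, −2.00 for PVR, −1.44 for SLC7A11, −1.20 for HLA-G and 1.70 for GLUL. PMAIP1 differed by −0.91.

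The first pattern is the lower response of actin and matrix genes in clone 8: TAGLN −1.77, ACTA2 −1.36, ACTN1 −1.13, TPM4 −0.90, FN1 −1.17, COL4A1 −1.07, LOX −0.97 and ID3 −0.82, with list medians of −0.26 (actin), −0.24 (matrix) and −0.38 (mesenchymal markers, with IL6ST at −0.88). Scaling between the arrays is argued against, since after quantile normalization the members of the actin and matrix lists still had a median of −0.22 in the clone 8 pair. A lower share of mesenchymal cells stays open. All 13 mesenchymal markers had a median of −0.026 in the clone 8 pair (SD 0.38), where the 49 actin and matrix genes had −0.21. The gap is within that SD, which is of single markers and not of their median, so it does not decide. In that pair 9 of the 13 markers lay below 0. A lower response than in the iA50 clones was seen for 11 of the 13, in part because the markers were higher in the + cultures of the iA50 clones (median 0.20, 1 of 13 below 0). Variation between 2 cultures of clone 8, in density or handling for example, cannot be told apart from the state, because the number of pairs is 1. An effect of the state that needs the iFA50 construct stays open as well, as a hypothesis that these arrays could not test, since construct and clone coincide.

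The second pattern is the higher level of cell division genes in clone 8 (median 0.93). A difference in scale that quantile normalization removes is argued against as the whole cause, since the median was then still 0.78. Scaling to the spike-ins lowered it to 0.28, but that scaling moves every gene of an array alike and so says nothing about the list against other genes. RNA quality cannot be told apart from clone, because the log2 ACTB 3′ to 5′ ratio was higher in clone 8 by 0.51 and no array of another clone reached that ratio, although the GAPDH ratio was higher by only 0.090. A faster dividing clone is a biological explanation that may hold and was not tested, as no growth measure accompanies the arrays.

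The third pattern is that no probe set or list passed the threshold over all 3 clones and that the differences of clone 8 did not run with those of the iA50 clones. Noise of dim probe sets is argued against as the whole cause of the missing correlation, because in the brightest 25% of probe sets the higher of the correlations of clone 8's differences with those of an iA50 clone was still −0.0393. Over the 10 splits of the 6 arrays into 3 and 3, with clone as a block, the real split gave 0 probe sets and 0 lists and the highest of the others 3 and 2, while the 3 others that part the arrays of every clone, as the real one does, gave 0 probe sets and up to 2 lists. The splits are too few for a share under 0.05, and no split can give fewer than 0. Different responses of the clones, no response in any, or shared changes that did not pass stay open. Shared changes under 2-fold were not simulated, and larger ones only with 200 changes per set, so recovery with fewer changes is not known. PLCD1 (mean 1.36) and MMP24OS (1.57), for example, were higher in each clone and did not pass.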

How the results depend on the processing

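The alternatives with an offset of 500, the scaling to spike-ins and the list tests on contrasts other than all 3 clones were chosen after seeing the data. The comparison of all 3 clones stayed at 0 probe sets under each offset, scaling, filter, prior and block setting run, and at 0 gene lists under each of these but the prior, which was not run for lists, and ranged from 0 to 28 probe sets and from 0 to 2 lists when 1 clone was left out. Calls that rest on 1 residual degree of freedom were the least stable. The 13 calls of the iA50 clones became 2 with quantile normalization, 28 when fitted without the clone 8 arrays and 125 with the 60% filter. They became 0 with no filter, 0 with one prior variance and 0 with no replicate block. That block was the only pairing tested. Dropping it was otherwise run only on the comparison of all 3 clones and its lists, which had 0 calls to lose, and not on the calls of the difference. The 141 calls of the difference became 91 with an offset of 500, 11 with quantile normalization (all 11 shared with the 141), 0 with no filter, 416 with the 60% filter (104 shared) and 0 with one prior variance. For TAGLN the adjusted p of the difference in limma ran from 3.6e-14 to 0.377 over 8 alternatives, and for ACTA2 from 3.2e-08 to 0.408, with the same sign in each. Of the probe sets at least 2-fold apart in clone 8 (326), 204 were counted with an offset of 500, 3113 with no filter and 63 with the 60% filter. Clone 8 against clones 6 and 9 (4988) gave 8377 with spike-in scaling and 3817 and 4147 with clone 9 or 6 left out. The 21 probe sets at least 1.5-fold apart the same way in all 3 clones became 13 with an offset of 500, 370 with no filter, 2 with the 60% filter, 2 at 2-fold, and 101 to 121 over the remaining pair when 1 clone was left out. Among lists, the 1 call of the iA50 clones became 2 with median scaling, 0 with no filter, 0 with an estimated correlation, 0 with fry and 2 with the mean of a gene's probe sets. The 3 calls of the difference became 0 with an estimated correlation and 0 with fry, and the 5 of clone 8 became 0 with an estimated correlation and 8 with fry, which tests a list on its own. PEG10 in clone 8 against the others ranged from −0.12 to 5.33, and KAT5 in all 3 clones from −0.068 to 0.057, when 1 clone was left out. Fewer or more probe sets tested is part of each filter setting, and for the other settings the cause was not tested. Among the probe sets run under these settings no other direction turned, and most list members named in the text were not run. Leaving out clone 6 or 9 leaves no residual degrees of freedom for the iA50 response and for the difference, so those gave values with no test. How far dim probe sets stand above background cannot be read from the deposited intensities, which limits the genes with large differences near the filter.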

Other observations

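The placement of lists within the clone 8 pair was chosen after the differences per gene had been seen, has no replicate, and gives no p-value. The random lists were drawn gene by gene and lack the shared variation of related genes. A list of genes that vary together can therefore reach an extreme percentile in a single pair. TAGLN and ACTA2 also entered the actin list from the study. Besides the actin and matrix lists, whose medians of −0.26 and −0.19 lay at percentile 0 of 10000 random lists of matched level, the unfolded protein response genes had a median of −0.15 (percentile 1.25), with ASNS, asparagine synthetase, at −0.77 and the chaperone HSPA5 at −0.40. The heat shock genes had −0.15 (percentile 1.89), with HSPH1 at −0.78 and BAG3 at −0.34. The oxidative phosphorylation genes lay on the other side, at 0.12 (percentile 98.3), with COX6A1 at 0.31 and NDUFB5 at 0.30, and the immediate early and NF-kB genes at 0.16 (percentile 96.5), with CXCL2 at 0.71 and CCL2 at 0.68 but MYC at −1.22.

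Markers of other cell types and states lay nearer the middle in the clone 8 pair: percentile 33.2 for mesenchymal, 43.3 for noradrenergic, 8.15 for epithelial, 92.3 for Schwann cell (2 genes) and 55.0 for blood cell markers. So did interferon response (87.9), hypoxia (87.8), APP processing (74.6), proposed AICD targets (72.6), p53 targets (65.4), ribosomal proteins (64.2), cholesterol synthesis (31.5) and cell division (15.5).

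The IGHG1 probe set read 4715 and 10180 in clone 6 (+ and −), 5316 and 15060 in clone 9, and 1998 and 6768 in clone 8. TPM1, a tropomyosin, had 4 kept probe sets, with clone 8 differences of −0.41, −0.61, −0.99 and −1.07.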
